A study of Bos taurus and Bos frontalis with 6 samples.

How the data were processed

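RNA from the longissimus dorsi, the long muscle of the back, was sequenced in 6 libraries, 3 from Gayal (Bos frontalis) and 3 from Banna cattle (Bos taurus). Per the labels' protocols, RNA was extracted from frozen muscle with TRIzol, and paired-end reads were made on an Illumina HiSeq instrument. The submitters' processing notes name HISAT2 2.0.4 and the cattle genome build ARS-UCD1.2. The gene annotation, the counting program and the use of strand are not given in the sources used here. Both species were therefore read against a cattle genome, and reads from genes that overlap or share sequence with a copy could have been divided between them.

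The deposited values were estimated counts, 1 whole number per gene and library, with no normalization for depth. They were taken as estimated counts because low values piled up at multiples of a step rather than at every whole number. The step was estimated in each library from values up to 60 as the spacing whose multiples, rounded up, held the largest excess of genes. It was 3.33 counts in Banna replicates 1 and 2, 3.31 in Gayal replicate 1, and 4 in the other 3 libraries. The design fixed before the data were examined assumed read counts; the same count test was kept, and rounding to whole numbers left every value as deposited. A deposited sample sheet gave each library a batch letter and a fibre class. Banna replicates 1 and 2 and Gayal replicate 1 were batch A, and Banna replicate 3 and Gayal replicates 2 and 3 were batch B. The sheet does not say what the batch stands for. The fibre class was coarse for all Banna libraries and fine for all Gayal libraries, so fibre class and species were 1 factor.

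The table held 27270 Ensembl cattle gene identifiers, of which 8273 were at 0 in all 6 libraries. It did not pair identifiers with gene symbols, and 0 of the identifiers matched the reference table used here. As a result, the 32 lists of muscle, fat, connective tissue and blood genes fixed before the data were examined could not be tested. The rule for the genes to be named, which needed symbols, could not be applied either. At most 2 identifiers per direction are printed. They are those with the smallest p in the fit with a batch term, chosen after their values were seen.

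Species were compared as fixed before the data were examined, with edgeR 4.0.16 in R 4.3.3. Library totals were scaled by TMM factors, genes with low counts were removed with filterByExpr, which left 14112 genes, and a robust quasi-likelihood F test was run with species as the 1 term. Adjusted p is the Benjamini-Hochberg value and the threshold was 0.05, with no minimum fold. The standard error of a log2 difference was its size divided by the square root of F. Because the sample sheet named batches, a fit with species and batch as terms, a test of the batch term, a species by batch interaction and a fit within each batch were added after the data were examined. The fit without batch left 4 residual degrees of freedom, the fit with batch 3, and each within-batch fit 1, where the species with a single library was assumed to vary like the other. For a gene with few Banna counts, counts were divided by the step, rounded and pooled by species, and the ratio was taken after dividing each pool by the sum of its TMM-scaled library totals over the step. Levels are TMM-scaled CPM, and principal components and correlations used log2 CPM with a prior count of 2. Single values per library were compared with a two-sided exact permutation test, whose smallest p with 3 libraries against 3 is 0.1.

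Alternatives were DESeq2 1.42.0, limma 3.58.1 with voom, DESeq2 size factors, upper-quartile factors and library totals in place of TMM, no filter or a stricter filter on low counts, and removal of the 20 most abundant genes. Stricter thresholds, the replicate number as a block and leaving out each library were also run. The stricter filter asked for 1 CPM in at least 3 libraries and a mean of 50 counts. On the real counts DESeq2 was run on all genes, without filterByExpr. Fits limited to genes with a symbol or without mitochondrial genome genes were not run for want of symbols.

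The fits were tested on simulated counts for 14112 genes in 3 Gayal and 3 Banna libraries with 200 changed genes, 50 of each size. The changed genes were drawn from those with a mean of at least 1 CPM. Counts came from a single draw with the gene dispersions of the edgeR fit with a batch term. The setting may therefore favour edgeR over DESeq2. With edgeR and no batch term, 36% of the genes changed by a log2 of 4 and 70% of those changed by 6 were called, and 0 of 54 calls were false. With a batch term these shares were 80% and 92%, and 8 of 111 calls were false, 7.21%. DESeq2 with a batch term called 98% and 96%, and 77 of 214 calls were false, 36%. At a log2 of 2 the shares were 2% with edgeR, 32% with edgeR and a batch term, and 68% with DESeq2 and a batch term. The age in the labels is 3.5 ± 0.5 years for all 6 samples, and the sex of the animals is not given in the sources used here. Nothing in the labels states that the 3 samples of a species came from separate animals, so p-values measure the spread between these samples. Floors for genes at 0, and the 95% exact Poisson interval of a ratio of pooled steps, cover counting error only.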

Results

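Muscle transcriptomes of Gayal and Banna cattle, described in the series title as differing in beef quality, were compared to find genes expressed at different levels in the longissimus dorsi. The total of estimated counts was 89392869 in Banna replicate 1, 87209182 in replicate 2 and 90313051 in replicate 3. It was 53979857 in Gayal replicate 1, 77691180 in replicate 2 and 74125305 in replicate 3. Gayal libraries held 68598781 ± 12785287 counts and Banna libraries 88971701 ± 1594220 (SD, n = 3), a ratio of 0.771, with p = 0.1 in a two-sided exact permutation test, the smallest p this design can give. Divided by each library's step, the spacing of 3.31 to 4 counts at which its low values piled up, the totals were 18087412 ± 1604090 in Gayal and 25203971 ± 2297447 in Banna (SD, n = 3). The number of genes above 0 was 15490 ± 517 in Gayal and 15960 ± 332 in Banna (SD, n = 3; exact permutation p = 0.3, two-sided). The 10 genes with the highest counts held 29.3 ± 2.89% of the counts in Gayal and 32.2 ± 4.09% in Banna (SD, n = 3; exact permutation p = 0.4, two-sided).

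The genes printed here had the smallest p in each direction in the fit with a batch term. Both that were higher in Gayal muscle were also counted in every Banna library, at far lower levels. ENSBTAG00000049167 was at 270 ± 79.5 CPM in Gayal and 1.57 ± 0.959 CPM in Banna (SD, n = 3), a 172-fold difference of means. Its estimated counts were 16456 to 20335 in the 3 Gayal libraries and 64 to 242 in the 3 Banna libraries. ENSBTAG00000031764 was at 15.8 ± 13.1 CPM in Gayal and 0.0883 ± 0.0269 CPM in Banna (SD, n = 3), from 579 to 1738 counts in Gayal and 6 to 11 in Banna. The Banna counts of this gene came to only 2 to 3 steps per library, and the ratio of pooled steps between the species, each divided by its TMM-scaled library totals in steps, was 157, with a 95% exact Poisson interval of 75.8 to 391 that covers counting error only. In the other direction, ENSBTAG00000008625 was at 5.75 ± 2.09 CPM in Gayal and 29.1 ± 2.41 CPM in Banna (SD, n = 3), 5.06-fold lower in Gayal. ENSBTAG00000004046 was at 0.908 ± 0.0912 CPM in Gayal and 8.44 ± 2.79 CPM in Banna (SD, n = 3), 9.3-fold lower in Gayal. For these 4 genes all Gayal libraries lay on 1 side of all Banna libraries, which their choice by smallest p makes likely. Over all genes tested, 10.4% separated the species in this way. The files do not pair the identifiers with gene names.

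**Figure D1:**
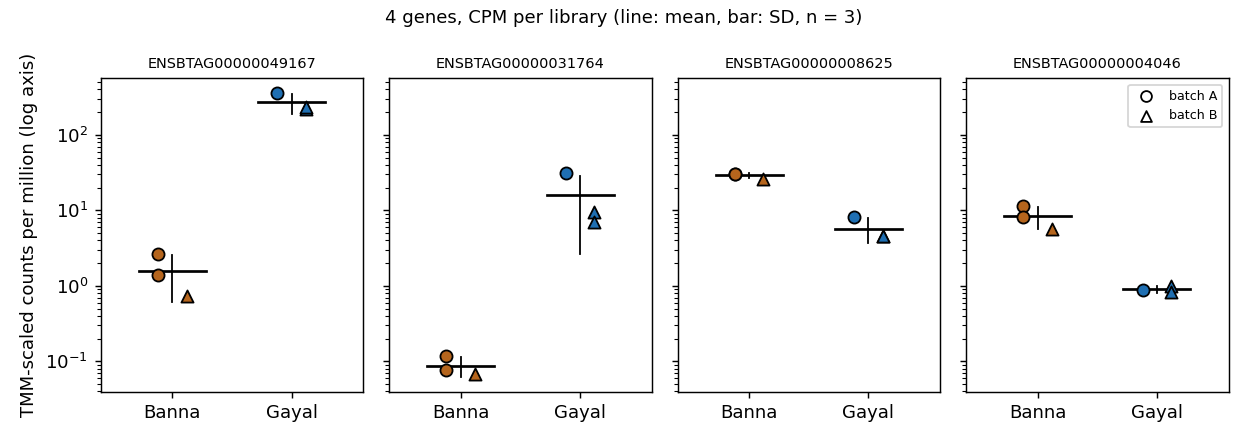
TMM-scaled CPM (log axis) of 4 genes in each library, with Banna in brown and Gayal in blue, batch A as circles and batch B as triangles, the group mean as a horizontal line and the SD (n = 3) as a vertical bar. The first gene was 172-fold higher in Gayal, the second was higher against only 6 to 11 counts in Banna, and the other 2 were 5.06-fold and 9.3-fold lower. The species did not overlap, which the choice of these genes by smallest p makes likely.

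With species as the 1 term, edgeR called 0 of 14112 genes higher and 0 lower in Gayal. At an unadjusted p under 0.05 there were 720 genes, and the smallest adjusted p was 0.122. If no gene differed and p were uniform, 705.6 genes would arise. That number is no firm reference here. The 8 other splits of the libraries that follow neither species nor batch all gave fewer, 148 to 470 genes at that p. On the same design DESeq2 called 88 genes higher and 84 lower, and limma-voom called 1 higher and 0 lower. DESeq2 was run without the low-count filter and gave 16480 genes an adjusted p, so its counts cover a different set of genes. The edgeR log2 difference of ENSBTAG00000049167 was 7.42 (SE 0.701, adjusted p = 0.122) and that of ENSBTAG00000031764 was 7.45 (SE 0.832, adjusted p = 0.141). For ENSBTAG00000008625 it was -2.34 (SE 0.404, edgeR adjusted p = 0.462), and for ENSBTAG00000004046 it was -3.21 (SE 0.466, edgeR adjusted p = 0.311). DESeq2 on the same design called all 4, with adjusted p of 7.19e-31, 3.04e-19, 0.000128 and 8.98e-08 in this order, and limma-voom called ENSBTAG00000049167 (adjusted p = 0.0133) and none of the other 3.

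The libraries were set apart by batch more than by species. The first principal component held 52.7% of the variance, and the batch letter accounted for 92.6% of the spread along it, against 20.8% for species. Each share was computed without the other factor, and the batches are not balanced over the species, so the shares overlap. Species accounted for 71.6% of the spread along the second component, which held 16.5% of the variance. Much of that spread came from Gayal replicate 1, at -90.65. Gayal replicates 2 and 3 were at -20.84 and -11.16, and the Banna libraries at 30.26 to 51.38. The mean correlation of log2 CPM across genes was 0.913 for the 4 pairs of libraries of different species in the same batch. For the 4 pairs of the same species in different batches it was 0.858. With species in the edgeR fit, 1091 genes were higher and 973 lower in batch B than in batch A, 14.6% of the genes tested, with a median absolute log2 difference of 1.88. That count of 2064 was 1258 without Banna replicate 1 and 1205 without Banna replicate 2, and it was 0 without Banna replicate 3 or any 1 of Gayal replicates 1, 2 and 3. The median absolute log2 difference over all tested genes was 0.829 between batches and 0.396 between species in the same fit.

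**Figure D2:**
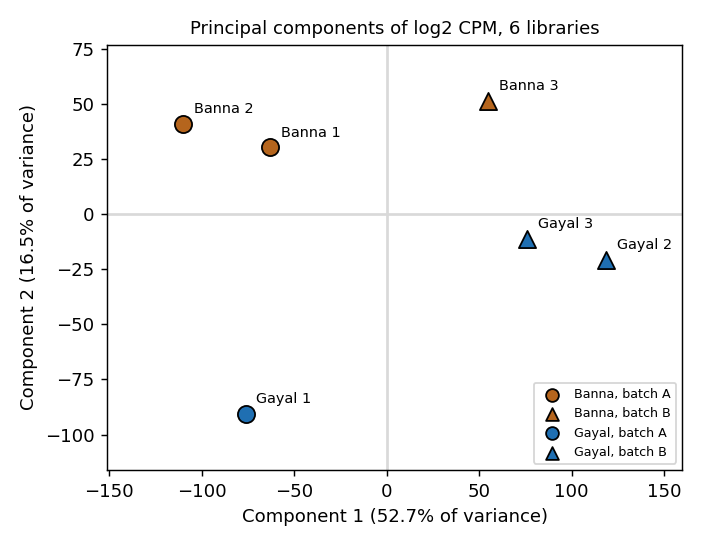
First principal component (52.7% of the variance) against the second (16.5%) of log2 CPM, 1 point per library, with Banna in brown and Gayal in blue, batch A as circles and batch B as triangles. The 3 batch A libraries lie at negative and the 3 batch B libraries at positive values of the first component. The species part along the second, where Gayal replicate 1 lies far from the other Gayal libraries.

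With batch as a term, 6 genes were higher and 0 lower in Gayal in edgeR, with the smallest adjusted p at 0.00858. The genes at an unadjusted p under 0.05 numbered 1123, where 705.6 would arise if no gene differed and p were uniform. The 8 splits that follow neither species nor batch all gave fewer than the species split, 250 to 993. DESeq2 with the same terms, without the low-count filter, called 430 higher and 228 lower of 18997 genes with an adjusted p. In limma-voom 10 were higher and 3 lower. In libraries simulated for this comparison, 36% of the DESeq2 calls and 7.21% of the edgeR calls were false. Those libraries held 200 changed genes among the 14112 left by the edgeR filter, and their counts had no steps. The false shares therefore need not hold for the real calls. All 3 Gayal libraries were above all 3 Banna libraries for each of the 6 genes. For 5 of them the log2 difference was between 3.88 and 7.87, or 14.8-fold to 235-fold. Their ratios of pooled steps, which take no account of batch, were lower, at 9.44 to 160. The gene at 7.5 had as few as 0 steps in a Banna library and 14 in all, with a ratio of pooled steps of 74. Its 95% exact Poisson interval was 43.8 to 136, for counting error only. The sixth was at 0 in all 3 Banna libraries and at 26.6 ± 16 CPM in Gayal (SD, n = 3), at least 213-fold higher against a floor of 3 steps per library. ENSBTAG00000049167 had a log2 difference of 7.87 (SE 0.458) and ENSBTAG00000031764 one of 7.69 (SE 0.508), each with an edgeR adjusted p of 0.00858. The differences of ENSBTAG00000008625, at -2.22 (SE 0.279), and ENSBTAG00000004046, at -3.05 (SE 0.411), did not pass with edgeR's adjusted p of 0.141 for each. Both passed in DESeq2 (adjusted p of 3.52e-10 and 5.71e-10) and in edgeR without a filter on low counts (adjusted p of 0.0404 and 0.0483). The count of 6 was 0 without Banna replicate 1, 0 without Gayal replicate 1 and 2 without Gayal replicate 3. It was 4 without Banna replicate 3, 4 without Gayal replicate 2 and 7 without Banna replicate 2, with 2, 3 and 5 of the 6 genes among them. ENSBTAG00000049167 was not called without Banna replicate 1, Banna replicate 3 or Gayal replicate 1 (edgeR adjusted p of 0.124, 0.0541 and 0.183), while its log2 difference stayed between 7.49 and 8.27. ENSBTAG00000031764 was not called without Banna replicate 1 or Gayal replicate 1 (edgeR adjusted p of 0.124 and 0.2), and its log2 difference stayed between 6.89 and 8.25.

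Since no library of 1 species overlapped the other for these 4 genes, their direction within each batch was fixed, and only the sizes are given. In batch A, with 1 Gayal and 2 Banna libraries, the log2 difference was 7.49 for ENSBTAG00000049167, 8.25 for ENSBTAG00000031764, -1.91 for ENSBTAG00000008625 and -3.5 for ENSBTAG00000004046. In batch B, with 2 Gayal libraries and 1 Banna library, the values were 8.33, 6.95, -2.48 and -2.58 in the same order. In edgeR, 129 genes were higher and 10 lower in Gayal within batch A, and 9 were higher and 3 lower within batch B. Each of these fits had a single library in 1 species, Gayal in batch A and Banna in batch B, assumed to vary like the other species, with 1 residual degree of freedom. The species by batch interaction called 0 genes in edgeR, with a smallest adjusted p of 0.119. At an unadjusted p under 0.05 it gave 931 genes, where 705.6 would arise if no gene differed and p were uniform. DESeq2 and limma-voom were not run on the interaction.

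Across the 14112 genes, which are not independent replicates, the species difference in batch A and that in batch B had a Pearson r of 0.151 and a Spearman rho of 0.112. These differences came from separate libraries. The batch difference in Banna and that in Gayal had a Pearson r of 0.549. Of 296 genes at least 4-fold apart between the species in both batches, 202 had the same direction, 68.2%, with 105 higher and 97 lower in Gayal. That share was not computed for other arrangements of the libraries within the batches, so it has no reference. By Pearson r the real arrangement ranked 3 of 9, and the highest other reached 0.194. Over all 6 libraries, 641 genes were higher in every Gayal library than in every Banna library and 822 were lower. Together they were 1463 genes or 10.4% of those tested. Ties aside, each gene separates exactly 1 of the 10 splits, so the mean over the splits is fixed at 10%. That mean is no reference for the species split. The batches were separated by 43.2% of the genes, and the 8 splits that follow neither species nor batch by 3.9% to 7.71%.

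**Figure D3:**
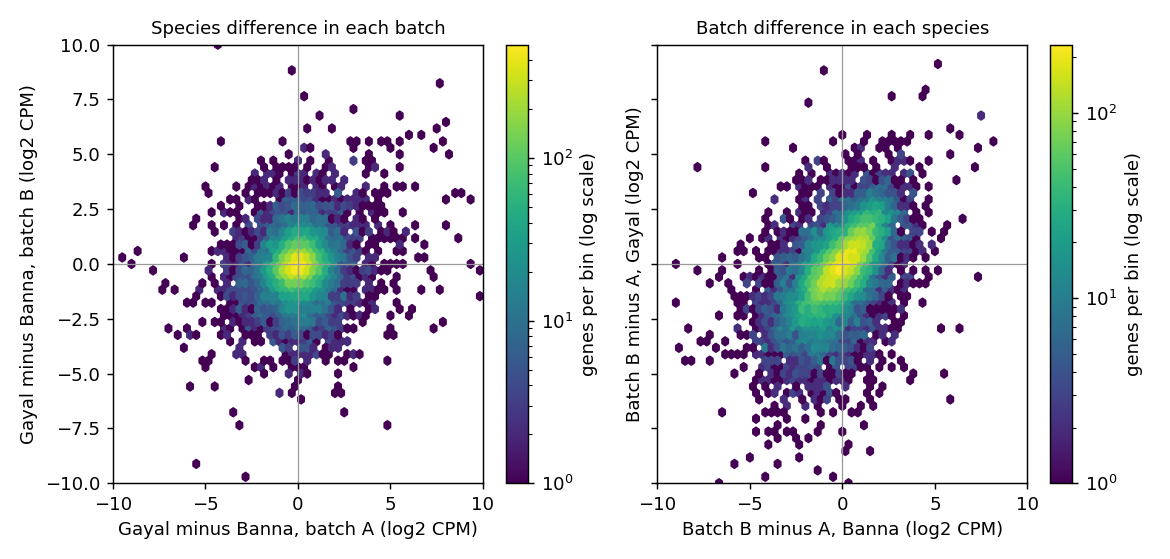
Hexagonal bins of 14112 genes, coloured by the number of genes per bin on a log scale, with both axes as differences of log2 CPM. At left, Gayal minus Banna in batch A against the same difference in batch B (r = 0.151), and at right, batch B minus batch A in Banna against the same difference in Gayal (r = 0.549).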

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

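Every fit with a batch term or within a batch, the counts divided by the step, the fit without robust estimation and the minimum counts of 20 and 50 were chosen after the data were examined. The causes of the shifts below were not tested, except that leaving out a library also leaves fewer samples. The main count of 0 higher and 0 lower in edgeR was unchanged in 17 settings for higher genes and 19 for lower genes, including all 6 left-out libraries. The stricter thresholds among these settings could only return 0, so they add nothing. It became 88 higher and 84 lower with DESeq2 and 1 higher with limma-voom. It became 6 higher with a batch term, 430 higher and 228 lower with a batch term in DESeq2, 10 and 3 with a batch term in limma-voom, 129 and 10 in batch A alone, and 9 and 3 in batch B alone. The 6 higher genes of the batch-term fit became 3 with library totals, 41 without a filter on low counts, 3 at an adjusted p under 0.01 and 0 to 7 with a library left out. The 0 lower genes of that fit became 2 without a filter, 1 with counts divided by the step and 0 to 1 with a library left out. All 6 genes were among the DESeq2 batch-term calls and 5 among those of limma-voom. Of the 6, 4 were called by DESeq2 without a batch term, where 2 had no adjusted p. Genes different between batches were 4444 with DESeq2 and 0 to 1258 with a library left out.

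With the replicate number as a block, edgeR called 0 genes higher and 0 lower in Gayal. Deviations of same-numbered libraries correlated at 0.253, -0.448 and 0.279 across genes. The negative value belongs to the pair from different batches, so the check follows batch, and neither it nor the labels show that the numbers pair the samples. The 4 named genes were chosen for a small p, so only their sizes are given: log2 differences were 7.08 to 8.33 for ENSBTAG00000049167, 6.52 to 8.25 for ENSBTAG00000031764, -2.68 to -1.91 for ENSBTAG00000008625 and -3.5 to -2.58 for ENSBTAG00000004046. The first component held 59% of the variance in the 500 most variable genes, and the ratio of totals was 0.718 after division by the step. Gene list tests and 2 planned subsets were not run for want of gene symbols. In the simulation, differences of a log2 of 2 were called in 2% of cases without and 32% with a batch term. Most differences of that size were thus missed by edgeR in that simulation, whose changed genes had a mean of at least 1 CPM.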

Other observations

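The comparisons in this part were chosen after the data were examined, except that the outcomes of leaving out each library for the 6 genes were stated before that test was run.

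Some genes were counted in 1 species only. At 0 in all 3 Banna libraries and with at least 10 counts in each Gayal library were 11 genes, with a median mean count of 64 and a highest of 1970 in Gayal. At 0 in all 3 Gayal libraries and with at least 10 counts in each Banna library were 15 genes, with a median mean count of 27.3 and a highest of 136.3 in Banna. Mean counts reached 100 in 4 of the first and 2 of the second. With a minimum of 20 counts the numbers were 7 and 3, and with 50 counts they were 3 and 1, so the side with more genes depended on the minimum.

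Among the 100 genes with the highest mean CPM, the median fold between the highest and the lowest library was 6.12, against 3.08 for all tested genes at 5 CPM or more. Banna replicate 2 was the lowest of the 6 libraries in 40 of the 100 and the highest in 22, and it was at least 4-fold below all others in 18 and at least 4-fold above all others in 2. All libraries of 1 species lay above those of the other in 12 of these genes, and all libraries of 1 batch above those of the other in 47.

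The first pattern was the difference between batches, 2064 genes with species in the fit. A counting scale or a few abundant genes as the source was argued against: either acts as about 1 factor per library, which adds the same value to every other gene, yet without the 20 most abundant genes the interquartile range of the log2 difference across genes was 1.67 for the batch split, against 0.946 for the species split and 0.72 to 0.985 for the 8 splits that follow neither. Banna replicate 2 alone was argued against by the 1205 genes called in the fit without it (1258 without Banna replicate 1, and 0 without Banna replicate 3 or any 1 Gayal library). A different read length could not be told apart from the batch, since the step was 1.2 times as large in batch B and was 3.31 to 3.33 counts in all batch A libraries and 4 in all batch B libraries. A hypothesis for the step is that estimated counts were made from coverage with 1 fixed read length for batches of different read length, which the ratio of 1.2 may reflect but cannot decide, and a biological difference between the samples of the batches stays open and untested.

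The second pattern was the 6 genes higher in Gayal with a batch term. Leaving out libraries could not decide whether the calls rested on a single library, since it also leaves fewer samples. Separation of the species fixed the sign of these genes but not their size. The smallest of their log2 differences with any library left out was 3.38, above the bound of 1 set beforehand. This value argues against a single library as the source of the differences, for these 6 genes only. These genes were chosen by their calls with all libraries, at log2 differences of 3.88 to 13.6, so a difference under 1 was unlikely from the start. Of the 6 genes, 0 stayed called without Banna replicate 1 or Gayal replicate 1, and 2 without Banna replicate 3 or Gayal replicate 3. Without Gayal replicate 2, 3 stayed called, and without Banna replicate 2, 5. The real grouping gave 6 calls, a count that 1 of the 9 splits that can be fitted with batch reached, and the highest other split gave 0; 9 splits are too few for a share under 0.05. Reads shared with gene copies and a species or fibre class difference in expression stay open and were not tested.

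Other groupings of the libraries bear on the counts without and with a batch term. Without a batch term the species split called 0 genes in edgeR, a count that 10 of the 10 splits reach by necessity, so it decides nothing; the highest other, the batch split, gave 2581, which points to batch as a structure of the samples. For that batch split, 1 of the 10 splits reached 2581, and the highest other split called 0. DESeq2 called 172 genes for the species split and 4031 for the batch split, the only 2 of the 10 splits to reach 172. The 8 splits that follow neither gave 20 to 45. With a batch term DESeq2 called 658, a count that 1 of the 9 splits reached, and the highest other split gave 491. These numbers of splits are too few for a share under 0.05. For the within-batch species differences, the real arrangement ranked 3 of 9 by Pearson r across genes, at 0.151, and the highest other arrangement reached 0.194.

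The third pattern was the genes counted in 1 species only. The splits that follow neither species nor batch gave at most 6 such genes on a side, and the batch split gave 31 and 5. For the 15 genes at 0 in Gayal, loss of Gayal reads on the cattle genome could not be told apart from a species difference. The numbers, 15 against 11, gave a two-sided exact binomial p of 0.557. That test cannot decide it, because it compares only numbers of genes and takes no account of the deeper Banna libraries. At this depth a gene at 0 may still be expressed below about 3 steps per library, and gene loss or silencing in 1 species stays open and untested.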
